A study of Mus musculus with 7 samples.

How the data were processed

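RNA from forelimbs of C57/Bl6 mouse embryos at embryonic day 11.5 was hybridised to 1-colour (Cy3) Agilent microarrays, with 75 ng of total RNA labelled per array, per the labels. The 7 arrays fall into 3 of microdissected apical ectodermal ridge (AER) and 4 of posterior limb surface ectoderm, as their titles name them. Each replicate was a pool of 2 to 3 mice, per the submitters' description, so the spread between arrays is a spread between pools. All 7 arrays sat on 1 slide and shared 1 scan time, per the file headers.

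For each array the authors gave a scanner file whose processed signal is an intensity on a linear scale, background-subtracted and detrended by the Agilent Feature Extraction software, with no scaling between arrays, per the file headers. The same deposited files hold the mean spot signal and the local background as intensity values before background subtraction. They also hold other columns, per the file headers, with a flag per spot for signal well above background, for saturation and for uneven or outlying spots. The deposited matrix of processed values is on a log2 scale, and its columns had the same sorted values on all 7 arrays, with column medians from 6.51757 to 6.51761. Per the submitters' processing notes the authors used limma, without a version or a step. Tested on the files, the normexp background correction with an offset of 50 followed by quantile normalization over all spots gave the authors' values to within 0.000108.

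The values compared here were computed from the deposited scanner files. Control spots were left out, as were spots called uneven or outlying, and the remaining spots of 1 probe were averaged on the log2 scale. Each array's 75th percentile over non-control probes was subtracted from the log2 processed signal, so a value of 0 is the 75th percentile of that array. Of 62976 spots, 59305 were not controls, and they held 55681 probes, of which 432 had more than 1 spot. A probe was kept when it was well above background on at least 3 of the 7 arrays, which kept 28282 probes, or 50.8%. Each gene was represented by the probe with the highest mean over all arrays. Probes took the gene name of their RefSeq accession (26300 probes, 47.2%), of their symbol (2044) or of an older symbol (355), and otherwise kept the name in the file (26982). Probe positions are on the mm9 build, per the file headers. The exon or untranslated region under a probe was not looked up.

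AER and ectoderm arrays were compared with limma 3.58.1 (lmFit and eBayes, limma's moderated test, two-sided) with the group as the single term, in R 4.3.3 with data.table, version 1.17.8. The residual degrees of freedom were 5, and the prior added 3.50. Adjusted p values are Benjamini-Hochberg values over all 20828 genes tested, with 0.05 as the threshold. Where every array of the lower group was at background for a gene, its fold was given as a lower bound ("at least"), with those arrays set to the dimmest signal called well above background on the same array, and the adjusted p is that of the fitted difference. Correlations between arrays were computed across genes, and genes are not independent replicates. Files were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with numpy 2.4.6 and matplotlib 3.10.9.

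The comparison, its test, the 22 gene lists and most alternatives were fixed before the data were examined. The lists were known AER genes, epidermal keratinocyte and periderm genes, pan-epithelial genes, limb mesenchyme genes, 5' Hox genes, Hedgehog pathway genes, FGF target genes, WNT ligands, WNT/beta-catenin target genes, BMP target genes, Notch pathway genes, cell cycle genes, apoptosis and p53 genes, cell junction genes, basement membrane genes, genes of split hand/foot and related limb malformations, and markers of erythroid, endothelial, macrophage, muscle progenitor, neural (with Schwann and melanoblast) and immediate-early or heat-shock expression. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 22 lists, and again with the correlation between genes estimated. Members were also counted with p adjusted over the list alone. Another 14 lists were added after the main results had been seen and are reported among the additional observations.

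Genes are named by a rule. It takes the 10 genes with the largest difference in each direction among those past the threshold, above background on all arrays of the higher group, with no overlap between the groups and with a proper gene symbol. It also takes every known AER gene and up to 4 members with the smallest p of each other list. A few genes that the rule takes are not reported here. Genes named outside that rule are said to have been chosen after their values were seen.

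Alternatives covered the background correction (normexp), quantile normalization, a 75th percentile over probes above background on all arrays, the authors' processed values, no filter and a stricter filter, the mean of a gene's probes, each probe on its own, eBayes with trend and robust options, array weights, the replicate number, the number in the file names or the slide row as a block, averaging the 2 ectoderm arrays that carry the same number in their file names, the fry test, and leaving out each array in turn. Centring each array on its pan-epithelial genes, and using AER replicate 3 as the single AER array, were added after the data had been seen. No pairing is stated, and the main comparison used none. Deviations of AER and ectoderm arrays with the same title number correlated across genes at -0.031, 0.194 and 0.131. The ectoderm array of the same number was the best match of AER replicates 2 and 3. AER replicate 1 correlated best with ectoderm replicate 3, at 0.182, so a pairing by title number is left open.

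The procedure was tested on simulated data with 20828 genes of which 200 were changed, in 10 runs. It recovered 1.49% of genes changed by 0.5 on the log2 scale, 40.6% of those changed by 1 and 96.1% of those changed by 2, and 5.70% of calls were false. With no change put in it made 0 calls, and a list shifted by 1 was called in 10 of 10 runs, beside 0.3 other lists per run. The simulated genes varied independently of one another, so these runs do not show how often lists of correlated genes are called. Far fewer genes were changed than the 3266 called in the real comparison. Each simulated gene also had the same spread on every array, while array weights ran from 0.247 to 2.74. The recovered shares therefore need not hold for the real comparison. The number of arrays limits the precision of every value. Of the members of the 22 lists, 27 had no probe past the filter and were not tested, among them Fgf17 of the known AER genes, as were 25 members of the added lists. The arrays of either group alone can carry a gene past the filter. No array was left out of the main comparison.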

Results

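Gene expression was measured in the forelimb bud of mouse embryos at embryonic day 11.5. The apical ectodermal ridge (AER), the thickened epithelium at the rim of the bud that sends growth signals to the tissue beneath it, was profiled on 3 arrays. Posterior limb surface ectoderm, the flat epithelium covering the bud, was profiled on 4 arrays as the control. The 75th percentile of the processed signal lay between 395 and 662 units on the AER arrays and between 296 and 520 on the ectoderm arrays. Spots well above background made up 48.7% to 55.2% on AER arrays and 48.9% to 51.1% on ectoderm arrays, and 0 probes were saturated. Across genes, arrays correlated at r = 0.980 to 0.988 within the AER group, 0.985 to 0.995 within the ectoderm group and 0.946 to 0.968 between groups. Over 253 probes printed 10 times, the typical SD between spots was 0.175 on AER replicate 1 and 0.168 on AER replicate 2 (log2). It was 0.0564 to 0.0597 on the other arrays. AER replicates 1 and 2 shared a slide column that held no ectoderm array. Ectoderm replicates 2 and 4, which carry the same number in their file names, were the closest pair. Their variance was 19.1 times the spot noise, against 60.3 to 95.4 times for other ectoderm pairs. Spot noise does not tell 2 pools from 2 arrays of 1 RNA, and this was left open: they were counted as 2 replicates, and 2266 genes differed when they were averaged, against 3266.

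The comparison asked which genes set the AER apart from posterior limb ectoderm as dissected. Fgf8, Fgf4 and Rspo2 were far higher in the AER arrays. Fgf8, the fibroblast growth factor made along the whole ridge, was 129-fold higher (95% CI 29.6 to 558; adjusted p = 0.00129; 3 AER and 4 ectoderm arrays, limma's moderated test). Its log2 difference was 7.01, and its other probes gave 4.55 and 7.32. Fgf4, a second ridge growth factor, was 88.0-fold higher (95% CI 19.9 to 390; adjusted p = 0.00209), with 1 of 4 ectoderm arrays above background and 14.0-fold with normexp and the 75th percentile. Rspo2, a secreted enhancer of WNT signalling, was 44.4-fold higher (95% CI 22.7 to 86.8; adjusted p = 7.62e-05; 17.6-fold with that processing). In the other direction, Kera, a proteoglycan of collagen fibrils, was at least 383-fold lower in the AER arrays (adjusted p = 2.38e-05; 78.4-fold with that processing). Myod1, a master regulator of skeletal muscle, was 137-fold lower (95% CI 73.2 to 257; adjusted p = 2.37e-05), with 1 of 3 AER arrays above background and 23.8-fold with that processing. For both genes, muscle and connective tissue carried with the dissected ectoderm stays open as an explanation.

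Of 20828 genes tested, 3266 (15.7%) differed between AER and ectoderm, 1464 of them higher and 1802 lower in AER. At least 2-fold differences were found for 1974 genes, 879 higher and 1095 lower. Genes with a RefSeq symbol made up 2499 of the differing genes, 1026 higher and 1473 lower. Among 2500 loci of long intergenic noncoding RNA, 146 were higher and 104 lower. The AER and ectoderm arrays did not overlap for 6321 genes (30.3%), against 5.71% by chance. For 144 genes at least 2-fold higher in AER, all ectoderm arrays were at background, as were all AER arrays for 240 genes at least 2-fold lower. The share of differing genes that were higher was 44.8%, and it was 57.4% when the 75th percentile was taken over probes above background on all arrays. Pan-epithelial genes were higher in the AER arrays by 1.58 on average (log2), and centring each array on them, an alternative added after the data had been seen, moved the median of all genes to -1.66 and left 1.18% of the calls higher. The centring assumes that pan-epithelial genes do not differ per epithelial cell, which was not tested. By construction it lowers every difference by the same amount. Directions are given relative to the 75th percentile, with the value under this centring where that turns a gene list or a gene past the threshold. Normexp with the 75th percentile, whose offset of 50 shrinks differences of dim genes by construction, gave a value smaller by over 1.5 times for 43 of 89 named genes past the threshold, with no change of sign, and these values are given as under normexp. Both slide rows held AER and ectoderm arrays: with the row as a block 2481 genes differed (1148 higher and 1333 lower), and within the rows 919 and 979 genes did. Row 1 held 1 AER array and row 2 held 1 ectoderm array, and their spread was assumed to be that of the 3 ectoderm arrays of row 1 and the 2 AER arrays of row 2. Without ectoderm replicate 4 the number of genes lower in AER was 1179.

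Beyond Fgf8 and Fgf4, several of the 10 genes with the largest fitted rise are known from other epithelia. For Gcg, Ambn, Krt23, Smpd3 and Clca1 all ectoderm arrays were at background. Their lower bounds lay under the 44.4-fold of Rspo2, which is outside the 10, so their place in this ranking is not established. Gcg, the precursor of glucagon, was at least 24.8-fold higher in AER (adjusted p = 3.20e-06), Ambn, an enamel matrix protein, at least 20.3-fold (adjusted p = 1.07e-05), and Krt23, an epithelial keratin, at least 27.7-fold (adjusted p = 0.000198). Smpd3, a sphingomyelinase, was at least 28.2-fold higher (adjusted p = 2.87e-05) and Clca1, a secreted protein of mucous epithelia, at least 16.0-fold (adjusted p = 2.20e-05). The tyrosine kinase gene Srms was 54.7-fold higher and Igfbpl1 48.9-fold, and they were above background on 1 and 2 of the 4 ectoderm arrays (both adjusted p = 0.00124). Under normexp the folds were 9.93 for Gcg, 6.52 for Ambn, 11.4 for Krt23, 9.36 for Smpd3, 6.09 for Clca1, 8.89 for Srms and 13.3 for Igfbpl1. All 3 AER arrays lay above all 4 ectoderm arrays for each of these genes. On the mm9 build, the Fgf8 probe lay on chromosome 19 from 45811355 to 45811414, the Fgf4 probe on chromosome 7 from 152051089 to 152051148, the Gcg probe on chromosome 2 from 62312685 to 62312744 and the Ambn probe on chromosome 5 from 88897416 to 88897475.

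Known AER genes rose as a group. Of 21 measured members, 16 were higher in AER, 0 were lower and 5 did not pass the test (18 and 0 adjusted over the list alone), with a median log2 difference of 3.09, or 2.72 with Sp9 and En1 at their bounds. It was 2.22 under normexp, 2.42 with normexp and quantile normalization and 2.43 with the authors' values. Camera gave adjusted p = 3.71e-15, and adjusted p = 0.0974 with an estimated correlation. Among transcription factor genes of the list, Sp6 was 17.5-fold higher (95% CI 10.4 to 29.3), Sp8 13.7-fold (95% CI 6.08 to 30.8), Sp9 at least 6.58-fold, Dlx2 15.8-fold, Dlx5 10.8-fold, Dlx6 8.51-fold and Msx2 10.4-fold, with adjusted p between 2.13e-05 and 0.00146. Under normexp Sp9 was 2.64-fold and Dlx6, above background on 1 of 4 ectoderm arrays, 2.27-fold higher. En1, which marks ventral limb ectoderm, was at least 1.71-fold higher (adjusted p = 9.83e-05; 1.44-fold with adjusted p = 0.0802 under normexp). The hyaluronan receptor gene Cd44 rose by 3.28 (2.49 under normexp, 2.66 with another probe), the BMP ligand gene Bmp4 by 2.28, Wnt5a by 2.06 and the Notch ligand gene Jag2 by 1.80 (log2; adjusted p from 4.79e-05 to 0.00126). Bmp7 was higher by 0.52 (adjusted p = 0.0393), a call lost when any array other than AER replicate 1 was left out, with adjusted p = 0.0628 without AER replicate 2, 0.0845 without AER replicate 3, and 0.102, 0.114, 0.0556 and 0.106 without ectoderm replicates 1 to 4. The members that did not pass were Gja1 (0.79, adjusted p = 0.118, and 0.0465 with array weights), Fgf9 (0.55, adjusted p = 0.0791, and 0.0278 with normexp and quantile normalization), Bmp2 (-0.18), Flrt3 (-0.27) and Trp63, the master regulator of stratified epithelium (-0.25). Under epithelial centring Gja1, Fgf9 and Bmp7 turned to -0.79, -1.03 and -1.06. Other probes of Trp63 gave 1.71, 2.06 and 1.80, and the mean of its probes gave 1.33 with adjusted p = 0.000535.

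The ectoderm arrays did not all lack ridge transcripts. Fgf8 had a mean log2 signal of 6.27 (SD 0.37, n = 3) in AER and -0.74 (SD 2.00, n = 4) in ectoderm, and ectoderm replicate 3 stood at 2.20 while the other ectoderm arrays lay at -2.33, -1.42 and -1.40. The mean of the known AER genes was 0.82 on ectoderm replicate 3, against -0.24 to 0.01 on the other ectoderm arrays and 2.70 to 3.13 on the AER arrays. Without ectoderm replicate 3, 2790 genes differed, 1263 of them higher in AER. Within the slide rows, the median difference of the known AER genes was 2.80 and 3.05. With AER replicate 3 as the single AER array, a choice made after the data had been seen, Fgf8 was higher by 7.27 with adjusted p = 0.0626.

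**Figure D1:**
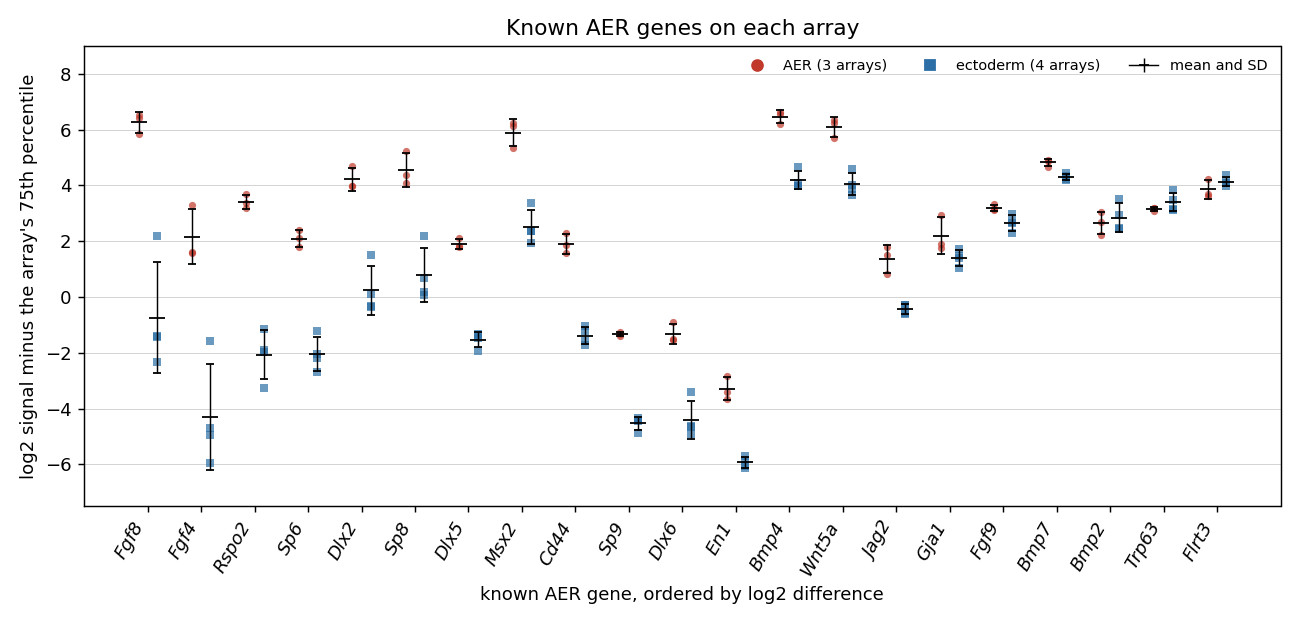
Each point is the log2 signal of a known AER gene on 1 array minus that array's 75th percentile, with the mean and SD of 3 AER arrays (circles) and 4 ectoderm arrays (squares) beside them. Fgf8 lies between 5.84 and 6.54 on the AER arrays and at 2.20 or lower on the ectoderm arrays. Bmp2, Trp63 and Flrt3 overlap between the groups, though other Trp63 probes gave differences of 1.71, 2.06 and 1.80. Centring on pan-epithelial genes turns Gja1, Fgf9 and Bmp7 to lower by its construction.

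Most pan-epithelial genes were higher in AER than in the covering ectoderm. Of 20 pan-epithelial genes, 16 rose, 0 fell and 4 did not pass (18 and 1 adjusted over the list alone; median 1.66; adjusted p = 4.15e-14, and adjusted p = 0.0974 with an estimated correlation). The membrane protease gene St14 rose 11.6-fold, the transcription factor gene Tfap2c 8.72-fold, the claudin gene Cldn7 6.09-fold, Tfap2a 3.57-fold and the epithelial adhesion gene Epcam 3.40-fold, with adjusted p of 0.00058 or less. Cell junction genes, 5 of which are also pan-epithelial, had 13 members higher and 2 lower of 20 (15 and 2 adjusted over the list alone). Their median was 1.49, or 1.37 with bounded genes at their bounds, and -0.08 under epithelial centring (adjusted p = 1.38e-08, and adjusted p = 0.0974 with an estimated correlation). The desmosomal cadherin gene Dsc2 rose by 2.85 (2.23 under normexp) and Cdh3, encoding P-cadherin, by 1.30 (-0.28 under epithelial centring). The gap junction genes Gjb2 and Gjb6 went the other way, 19.5-fold and 26.4-fold lower in AER (adjusted p = 6.39e-05 and 5.20e-05; Gjb6 16.1-fold under normexp). Muscle progenitor and limb mesenchyme genes were lower on the same AER arrays, with medians of -5.24 and -1.52. On single arrays, the mean of the pan-epithelial genes lay between 1.79 and 2.05 in AER and between 0.14 and 0.67 in ectoderm.

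Basement membrane genes were higher too, with 17 of 22 members up, 0 down and a median of 1.39, which became -0.19 under epithelial centring (18 and 1 adjusted over the list alone). Camera gave adjusted p = 1.04e-12, and adjusted p = 0.141 with an estimated correlation. Laminin chain genes were among them: Lamb3 rose by 2.79 (1.44 under normexp) and Lama5 by 2.08, and the laminin receptor gene Itga6 rose by 1.67, with adjusted p between 0.00012 and 0.000314. Epidermal keratinocyte and periderm genes were split, with 8 of 17 higher, 2 lower and 7 not past the test (10 and 2 adjusted over the list alone). Their median of 1.38 and mean of 0.61 differed in size, and the median was -0.19 under epithelial centring. Camera gave adjusted p = 0.00214, and adjusted p = 0.427 with an estimated correlation. The epidermal regulator Ovol1 rose by 2.84 (1.33 under normexp), and Perp, a desmosome gene, rose 3.02-fold. Krt15, a keratin of basal epidermal cells, was 48.6-fold lower in AER (95% CI 15.0 to 157; adjusted p = 0.00129), and 17.8-fold under normexp. Within the slide rows the epidermal medians were 1.44 and 0.56, and those of pan-epithelial genes were 1.48 and 1.48. Genes of split hand/foot and related limb malformations, which include Dlx5, Dlx6 and Trp63, had 6 of 10 members higher and 1 lower (8 and 1 adjusted over the list alone), with a median of 1.38 that was -0.20 under epithelial centring. Camera gave adjusted p = 2.56e-05 for them, and adjusted p = 0.0974 with an estimated correlation.

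Signalling targets of the ridge were raised in part. Of 9 FGF target genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.93 that was -0.65 under epithelial centring (adjusted p = 1.32e-06, and adjusted p = 0.0974 with an estimated correlation). The feedback inhibitor gene Spry1 rose by 2.00, the ETS factor gene Etv1 by 1.37 (-0.21 under epithelial centring) and Il17rd, another FGF antagonist, by 0.93 (-0.65 under it). Etv4, a further ETS factor gene, rose 3.03-fold. BMP target genes had 6 of 10 members higher and 1 lower (6 and 1 adjusted over the list alone), with a median of 0.81 that was -0.77 under epithelial centring (adjusted p = 0.00157, and adjusted p = 0.208 with an estimated correlation). The homeobox gene Msx1 was 17.6-fold higher (95% CI 9.58 to 32.4; adjusted p = 0.000192), and the inhibitor gene Smad6 rose by 0.85 (-0.72 under epithelial centring). Smad9 was at least 2.28-fold higher (adjusted p = 0.0146, 0.0588 without AER replicate 2, and 1.40-fold with 0.0644 under normexp), and its difference turned to -0.0017 under epithelial centring.

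WNT genes divided. Of 15 WNT/beta-catenin target genes, 9 rose, 3 fell and 3 did not pass (10 and 3 adjusted over the list alone), with a median of 1.31 that was -0.26 under epithelial centring (adjusted p = 0.00123, and adjusted p = 0.154 with an estimated correlation). The feedback inhibitor genes Rnf43 and Notum rose 6.16-fold and 2.82-fold (Notum -0.08 on the log2 scale under epithelial centring), while the stem cell receptor gene Lgr5 was lower by a log2 difference of -3.30 and the transcription factor gene Sp5 by -3.68 (adjusted p = 0.000101 and 0.000203; -2.59 and -2.67 under normexp). WNT ligands went both ways, with 5 higher and 4 lower of 12 (6 and 4 adjusted over the list alone). Their median was 0.39, and -1.19 under epithelial centring (adjusted p = 0.413). Wnt6 rose by 2.19, and Wnt9a and Wnt9b were lower, at -3.01 and -2.05 (adjusted p from 5.45e-05 to 0.000404; Wnt9a -1.59 under normexp).

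Hedgehog pathway genes had 0 of 12 members higher and 5 lower (2 and 5 adjusted over the list alone), with a median of -0.14, and 0.01 under quantile normalization (adjusted p = 0.301). The receptor and antagonist gene Hhip, above background on 1 of 3 AER arrays, was lower at -3.25 (-2.02 under normexp). The transducer gene Gli2 was lower at -1.70 and the co-receptor gene Boc at -1.73 (adjusted p for the 3 genes from 0.000661 to 0.00114). Cdon, another co-receptor, was lower at -1.45 (adjusted p = 0.0275), a call that was lost without AER replicate 1, 2 or 3 (adjusted p = 0.0521, 0.0797 and 0.0798) and without ectoderm replicate 2 or 4 (0.0578 and 0.0722). Notch pathway genes had 4 higher and 3 lower of 17 (4 and 6 adjusted over the list alone), with a median of -0.11 (adjusted p = 0.906). The Notch effector gene Hey1 rose by 2.55, while the ligand gene Dll3 and the receptor gene Notch2 were lower, at -5.24 and -1.09 (adjusted p = 0.00156, 5.30e-05 and 0.0016; Dll3 -3.47 under normexp). Other probes gave -3.59 for Dll3 and -0.97 for Notch2 (adjusted p = 0.0549).

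**Figure D2:**
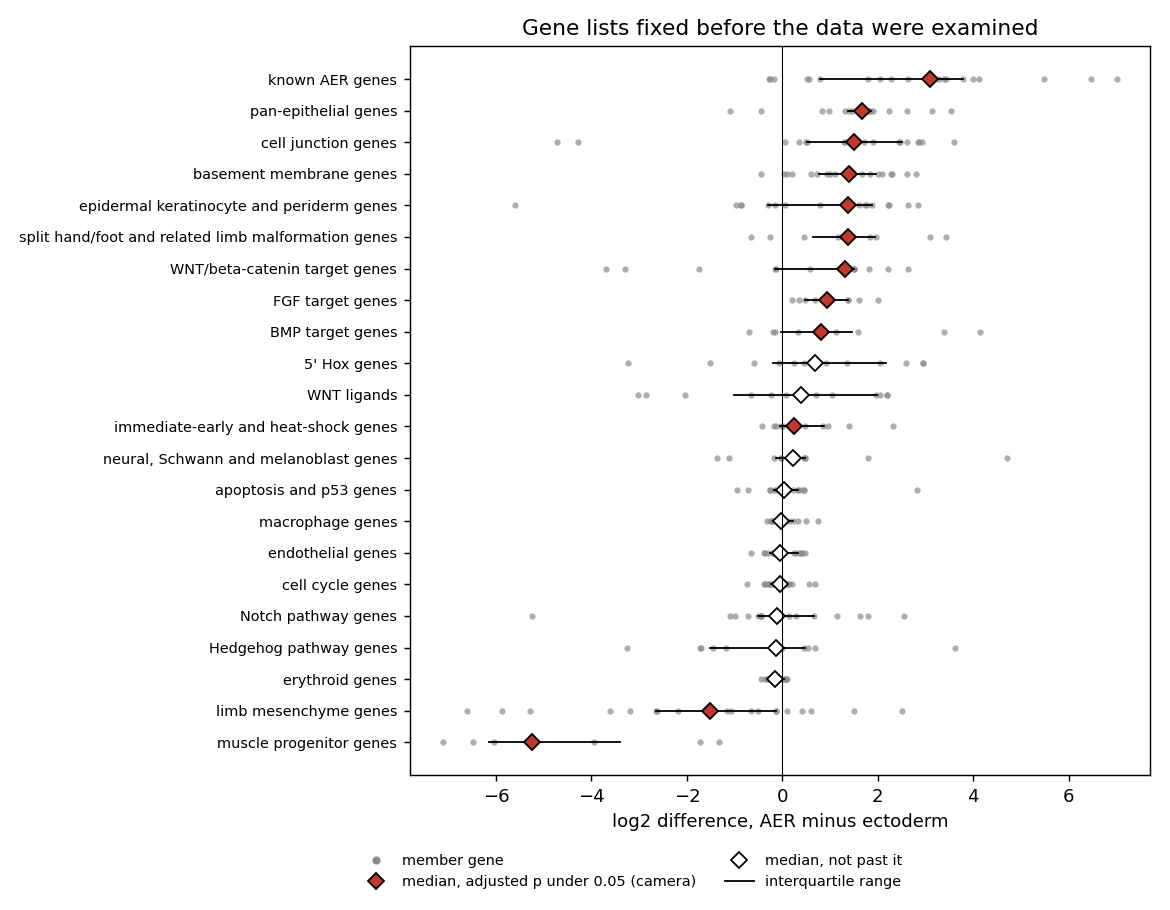
Each grey point is the log2 difference (AER minus ectoderm) of 1 member of a gene list, with the median as a diamond and the interquartile range as a line; filled diamonds passed camera's test at the preset correlation. Medians run from -5.24 for muscle progenitor genes to 3.09 for known AER genes. Epithelial centring lowers every difference by the same amount by construction, so the signs under it follow from the sizes shown and test nothing. Under it the known AER median is 1.51. Medians of the epidermal, junction, basement membrane, FGF, WNT, BMP, 5' Hox, limb malformation, immediate-early, neural and apoptosis lists turn negative.

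Genes that pattern the limb along its length were divided. Of 12 5' Hox genes, 5 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 0.68 that was -0.90 under epithelial centring and adjusted p = 0.0635. Hoxd13, which patterns the digits, was 7.73-fold higher (95% CI 3.85 to 15.5; adjusted p = 0.00237), as was Hoxc9 at 7.73-fold (adjusted p = 0.000607; 4.79-fold under normexp). Hoxa11, which patterns the forearm, was 9.40-fold lower (95% CI 6.39 to 13.8; adjusted p = 6.74e-05) and Hoxd9 2.88-fold lower (adjusted p = 0.000238). The mean of the list was 2.21 on ectoderm replicate 3, against 1.04 to 1.49 on the other ectoderm arrays and 1.99 to 2.26 on AER arrays, and the list's adjusted p was 0.00312 without ectoderm replicate 3 and 0.0428 without ectoderm replicate 1. It was 0.0325 with the slide row as a block, and the medians within the rows were 0.63 and 0.86.

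Muscle progenitor genes and many limb mesenchyme genes were lower in the AER arrays. All 8 measured muscle progenitor genes fell (8 adjusted over the list alone), with a median of -5.24 (adjusted p = 1.82e-09, and adjusted p = 0.0974 with an estimated correlation). The median was -4.29 under normexp, -4.25 with normexp and quantile normalization and -4.24 with the authors' values. Beside Myod1 these included Lbx1 and Pax3, which mark migrating muscle precursors, at -5.31 and -3.95, and the muscle cadherin gene Cdh15 at -5.18 (adjusted p from 2.37e-05 to 3.74e-05), with -4.35, -3.08 and -4.23 under normexp and -4.01 with another Lbx1 probe. Of 23 limb mesenchyme genes, 13 fell, 1 rose and 9 did not pass (13 and 3 adjusted over the list alone), with a median of -1.52 (adjusted p = 1.76e-05, and adjusted p = 0.0890 with an estimated correlation). The single riser was Lhx9, at 2.50 (adjusted p = 0.00356), named after its value was seen. Osr2 was at least 35-fold lower and Msc, also known from muscle precursors, at least 20.7-fold, the collagen gene Col1a1 12.2-fold and the cartilage regulator Sox9 6.30-fold (adjusted p from 3.50e-05 to 0.00012). Under normexp Osr2 was 9.17-fold and Msc 5.36-fold lower. Within the slide rows the muscle medians were -5.55 and -5.03, and the mesenchyme medians -1.46 and -1.48.

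The other 8 of the 10 genes with the largest fitted fall included further genes of connective tissue and muscle. For Agtr2, Rarres1 and Fitm1 all AER arrays were at background, so their place in this ranking rests on dim values and is not established. The collagen-binding proteoglycan genes Lum and Dcn were 273-fold and 142-fold lower in AER (adjusted p = 3.19e-05 and 2.43e-05), and Fst, encoding a secreted inhibitor of activin, was 120-fold lower (adjusted p = 3.82e-05). Agtr2, an angiotensin receptor gene, was at least 71.4-fold lower, Rarres1 at least 71.9-fold and Fitm1, a lipid droplet gene of muscle, at least 65.9-fold (adjusted p from 2.87e-06 to 6.50e-05). Mymx, needed for myoblast fusion, was 129-fold lower (adjusted p = 0.000198). Actc1, a cardiac and embryonic muscle actin gene, was 172-fold lower (95% CI 31.6 to 941; adjusted p = 0.00201), with an SD of 2.72 between the AER arrays. Under normexp the folds were 116 for Lum, 38.9 for Dcn, 19.4 for Fst, 18.2 for Agtr2, 15.1 for Rarres1, 12.7 for Fitm1, 27.3 for Mymx and 92.4 for Actc1. Lum, Dcn, Fst, Mymx and Actc1 were above background on 2 of the 3 AER arrays. The Kera probe lay on chromosome 10 from 97076230 to 97076289 (mm9).

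**Figure D3:**
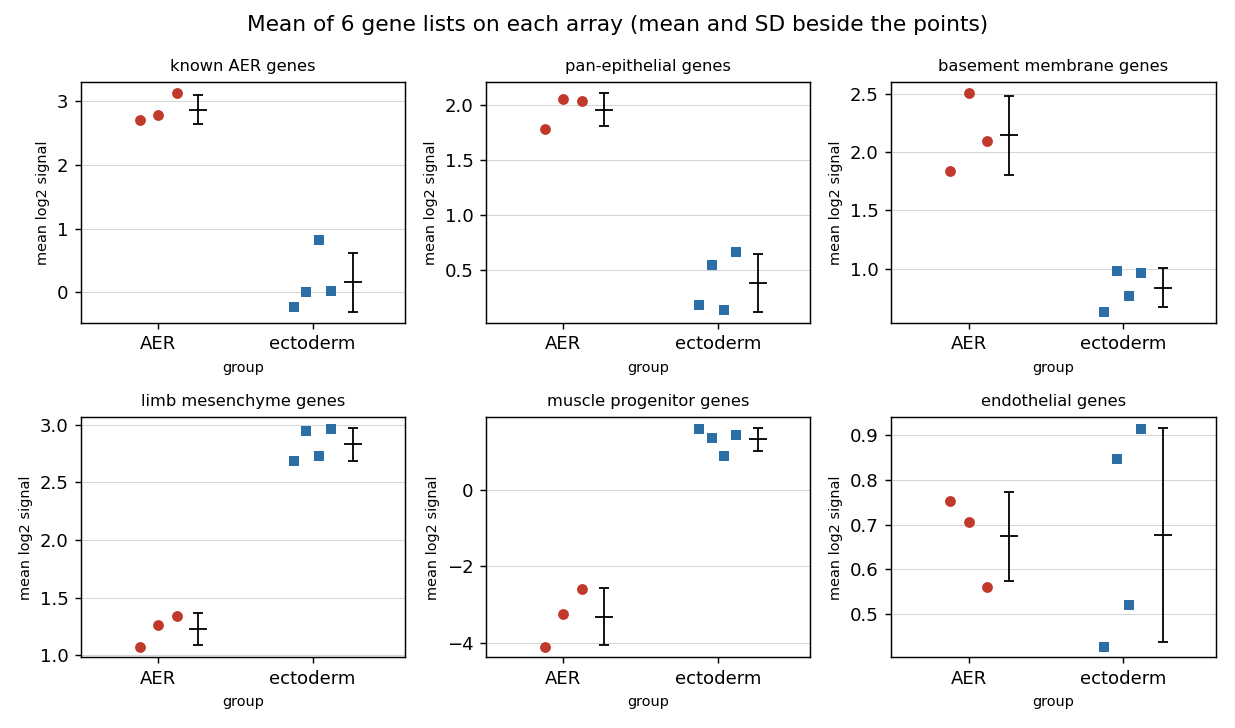
Each point is the mean log2 signal of a gene list on 1 array, with 3 AER arrays (circles), 4 ectoderm arrays (squares) and the mean and SD of each group beside them; the vertical scale differs between panels. Muscle progenitor genes lie between -4.10 and -2.60 in AER and between 0.89 and 1.59 in ectoderm, while endothelial genes overlap between the groups.

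None of the blood, vessel and immune marker lists passed the test in the main comparison. Of 15 erythroid genes 0 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of -0.16 (adjusted p = 0.590) that was 0.03 with normexp and the 75th percentile, 0.12 with normexp and quantile normalization and 0.13 with the authors' values. The embryonic globin genes Hbb-y and Hbb-bh1 gave -0.44 and -0.36 (adjusted p = 0.0722 and 0.132), Hbb-b2 -0.30 and the haemoglobin chaperone gene Ahsp -0.32. Without AER replicate 2 the erythroid list had adjusted p = 0.00856. Among 15 endothelial genes 1 fell (1 adjusted over the list alone), with a median of -0.04, a mean of -0.003, a test that leaned to higher (adjusted p = 0.689) and a median of 0.02 to 0.07 with normexp, with the authors' values and with the percentile over probes above background. The one was Sox18, a vessel regulator, at -0.66 (adjusted p = 0.0136, and 0.0555 without ectoderm replicate 4). Egfl7 gave 0.48 (adjusted p = 0.138, and 0.0446 without AER replicate 3), Eng 0.40 and Emcn 0.39. Of 13 macrophage genes 0 rose and 0 fell (0 and 0 adjusted over the list alone), and their median of -0.03, which was 0.08 with that percentile 0.02 with normexp and quantile normalization and 0.03 with the authors' values, differed in sign from their mean of 0.05 (adjusted p = 0.575). Ptprc gave 0.74 (adjusted p = 0.055), Fcgr1 0.49, Mrc1 0.32 and Csf1r -0.23, with -0.12 and 0.13 from its other probes.

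Neural, Schwann cell and melanoblast genes had 2 of 10 members higher and 1 lower (2 and 2 adjusted over the list alone), with a median of 0.22 that was 0.14 under normexp and -1.36 under epithelial centring (adjusted p = 0.186). Dct, an enzyme of melanin synthesis, was 26.1-fold higher (95% CI 9.61 to 70.9; adjusted p = 0.00136), with 1 of 4 ectoderm arrays above background and 4.33-fold under normexp (log2 4.71, and 3.88 with another probe), and the tubulin gene Tubb3 rose by 1.80 (adjusted p = 0.000518). The neuroblast gene Dcx was lower at -1.12 (adjusted p = 0.0195, and 0.0636 without AER replicate 1), and the Schwann cell gene Sox10 gave -1.38 (adjusted p = 0.0886). Of 25 cell cycle genes 0 rose and 1 fell (0 and 1 adjusted over the list alone), with a median of -0.06 (adjusted p = 0.689) that was 0.05 to 0.23 with normexp, quantile normalization, the authors' values and the percentile over probes above background. The one was the cyclin gene Ccne1, at -0.74 (adjusted p = 0.00761; -0.47 with adjusted p = 0.162 from another probe), while Mcm6 gave -0.38, Aurka -0.27 and Tyms 0.55 (adjusted p = 0.065, and 0.0497 without AER replicate 3). Apoptosis and p53 genes had 1 of 17 higher and 1 lower (1 and 1 adjusted over the list alone), with a median of 0.03 that was 0.18 under normexp and -1.55 under epithelial centring (adjusted p = 0.497). The cell death gene Pmaip1 was 7.07-fold higher (95% CI 3.19 to 15.7; adjusted p = 0.00602). Fas gave -0.95 (adjusted p = 0.0623, and 0.00253 without ectoderm replicate 3) and Cdkn1a 0.46.

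Of 12 immediate-early and heat-shock genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone), with a median of 0.25 that was -1.33 under epithelial centring. Camera gave adjusted p = 0.0309, and adjusted p = 0.208 with an estimated correlation. The call was also lost without AER replicate 2 (adjusted p = 0.0648) and without ectoderm replicate 3 (adjusted p = 0.0517). The AP-1 gene Junb was at least 1.74-fold higher (adjusted p = 0.000119; 1.46-fold under normexp), and the stress-response gene Atf3 was higher by 1.40 (adjusted p = 0.00478, -0.17 under epithelial centring, and 0.42 with adjusted p = 0.107 under normexp), while Ier3 gave 0.26. Hspb1, a small heat-shock protein gene, was higher by 0.96 (adjusted p = 0.0323). That call was lost without AER replicate 1 or 3 (adjusted p = 0.0529 and 0.0775) and without ectoderm replicate 1, 3 or 4 (0.0758, 0.0700 and 0.0549). The difference turned to -0.61 under epithelial centring.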

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

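The tests of a lower epithelial share alone, of the slide column and of known AER against pan-epithelial genes were chosen after the results were seen, as were the genes named here outside the naming rule, centring on pan-epithelial genes and the added gene lists, and the other tests had their predictions written before the values they measure were seen.

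Muscle progenitor genes were lower in the AER arrays, with a median log2 difference of -5.24. A lower epithelial share of the ectoderm arrays alone would raise all other cell types alike, and the values argue against it. The muscle median lay -5.20 from that of endothelial genes, and both medians had been seen before this test was chosen. A permutation test over genes gave p = 0.00017 (100000 permutations). It takes genes as independent and does not measure the spread between arrays. The 75th percentile scaling is excluded, since the muscle median was -5.19 under quantile normalization. A candidate explanation that stays open is that muscle and connective tissue was carried with the ectoderm: contractile and connective tissue genes were lower as well, and the higher of their medians was -2.08. Abundant members stood at 5.33 in ectoderm and 0.81 in AER (Tnnt1) and at 5.68 and 1.06 (Scx), the labels name no sort or gate that would remove such cells, and a difference between ridge and posterior ectoderm as dissected remains untested.

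Known AER genes were higher in the AER arrays, with a median of 3.09. A higher epithelial share alone stays open: the list median relative to pan-epithelial genes was 1.51, over the bound set for it. That value followed from main values already seen, and the bound left out the spread of pan-epithelial genes, which ran from -1.09 (Krt19) to 3.54 (St14). In a permutation test of the 2 lists over genes p was 0.00459, and it was 0.111 under normexp, where their medians lay 0.68 apart, while 6 of 21 members lay above the highest pan-epithelial gene in each, 5 of them in both. Relative to pan-epithelial genes, assumed not to differ per epithelial cell, 13 members were higher, 10 of them under normexp as well, and 6 were lower. Trp63 was among the 6 by its brightest probe, while its other probes gave main differences of 1.71, 2.06 and 1.80. The slide row is excluded, since the lower of the medians within the rows was 2.80. The values argue against the slide column but do not exclude it. The group difference in the list mean was 3.06 beside a trend over columns (SE 0.20). It was 3.12 beside a column factor (SE 0.18), resting on 1 array of each group in the shared column. AER replicates 1 and 2 lay in a column with no ectoderm array, so an effect of that column cannot be told from the group. AER replicate 3, which shared its column with ectoderm replicate 2, had a list mean of 3.13, against 0.01 there. A difference in gene expression between ridge and posterior ectoderm stays open, as untested.

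Hoxa13 (2.59, adjusted p = 0.0387) and Hoxd13 (2.95) were higher and Hoxa11 (-3.23) and Hoxd9 (-1.53) lower in the AER arrays. The values argue against more limb mesenchyme of all kinds in the AER arrays. Pan-mesenchymal genes had a median of -0.42, with 0 members higher and 4 lower of 11. As a list they did not pass camera's test (adjusted p = 0.0542), so this explanation is not excluded. A candidate explanation that stays open is distal mesenchyme carried with the AER and proximal mesenchyme carried with the ectoderm: the median of 7 distal genes lay 4.13 above that of 9 proximal genes. Distal genes such as Lhx2 (5.49 in AER, 2.56 in ectoderm) and Sall4 (1.84 and -1.72) were higher, and the labels name no sort or gate that would remove mesenchyme. Expression of these genes by the epithelium itself was not tested and stays open.

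Of 138 ectoderm values examined, 10 (7.25%) had 1 array far from the other 3, by a gap over Dixon's 95% critical value, where chance gives about 5%, and 7 of the 10 were on ectoderm replicate 3. On ectoderm replicate 3, Krt23 stood at -3.89 (others -6.26 to -6.09), Srms at -2.87 (others -6.17 to -5.97) and Dct at -3.35 (others -6.12 to -5.91). Msx1 stood at 3.35 (others 1.71 to 1.83), Bmp4 at 4.67 (others 3.99 to 4.08), Mrc1 at -1.62 (others -0.47 to -0.40) and Myod1 at 1.48 (others 2.41 to 2.48) on that array. Hbb-y stood at 10.36 on ectoderm replicate 2 (others 10.60 to 10.63). On ectoderm replicate 1, Dcx stood at 0.92 (others -0.08 to 0.05) and Sp5 at 1.95 (others 0.91 to 1.09).

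The counts of genes were set against all 35 splits of the 7 arrays into 3 and 4. For the 3266 differing genes, 1 split, the real one, gave a count as large, and the highest other split gave 80. The same held for genes higher in AER (1464, 1 split, highest other 37), for genes lower (1802, 1 split, highest other 43) and for genes with at least 2-fold differences (1974, 1 split, highest other 80). A rank of 1 among 35 is the most that these splits can show, so chance is unlikely for these counts but not excluded. For the 12 lists past camera's threshold the splits do not decide: 5 of the 35 gave as many, and the highest other split gave 13. That split set ectoderm replicates 1, 3 and 4 against all AER arrays and ectoderm replicate 2. It thus kept much of the contrast between the groups, and its lists are no measure of chance.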

How the results depend on the processing

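Epithelial centring and the use of AER replicate 3 alone were chosen after the data had been seen. Known AER, pan-epithelial, limb mesenchyme and muscle progenitor lists kept their direction and their call under all alternatives but the estimated correlation. Epithelial centring is not counted here, since it takes out the pan-epithelial mean by construction and shifts all other differences alike. The muscle list, with 3 of 8 members above background on all 7 arrays, was not tested with that filter. Signal over background limits dim genes, and 5 residual degrees of freedom limit small differences. The replicate block gave 2443 differing genes, 2213 of them shared with the main calls, and averaging ectoderm replicates 2 and 4 gave 2266, with 2243 shared. All 3266 main calls kept their sign under both, and 2279 did under epithelial centring. The cause of the changes below was not tested except where fewer arrays or genes were used.

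Genes with at least 2-fold differences numbered 1298 with normexp and quantile normalization, 1307 with the authors' values and 1261 above background on all 7 arrays. The immediate-early list lost its call with normexp and the 75th percentile (adjusted p = 0.0878), normexp and quantile normalization (0.0856), the authors' values (0.0854), background on all 7 arrays (0.0949), array weights (0.0716) and AER replicate 3 alone (0.123). The 5' Hox list passed with no filter (adjusted p = 0.0213), array weights (0.0289) and the slide row as a block (0.0325). With the mean of a gene's probes Trp63 turned to 1.33. With AER replicate 3 alone, which was assumed to vary like the ectoderm arrays, 1533 genes differed, 637 higher and 896 lower.

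Epithelial centring, which by its construction lowers every difference by the pan-epithelial mean, gave 19804 differing genes, 233 higher and 19571 lower, 18650 by at least 2-fold. The 5' Hox, WNT ligand and neural lists then passed as higher than other genes (adjusted p = 5.15e-07, 0.00442 and 0.0159), with medians of -0.90, -1.19 and -1.36 against -1.66 for all genes. Genes with a main difference between 0 and 1.58 turn sign by that construction, whether called or not, so these changes test nothing: Smad9 (-0.0017), Notum (-0.083), Atf3 (-0.17), Etv1 (-0.21), Cdh3 (-0.28), Hspb1 (-0.61), Il17rd (-0.65), Smad6 (-0.72), Gja1 (-0.79), Ptprc (-0.84), Tyms (-1.03), Fgf9 (-1.03), Bmp7 (-1.06), Fcgr1 (-1.09), Egfl7 (-1.09), Cdkn1a (-1.12), Eng (-1.17), Emcn (-1.19), Mrc1 (-1.26) and Ier3 (-1.32).

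With an estimated correlation all 12 called lists lost their call: adjusted p was 0.0974 for the known AER, pan-epithelial, FGF, junction, limb malformation and muscle lists, 0.427 for the epidermal, 0.0890 for the limb mesenchyme, 0.154 for the WNT target, 0.208 for the BMP, 0.141 for the basement membrane and 0.208 for the immediate-early list. By fry, which tests a list on its own, the epidermal list did not pass (0.0975), and the Hedgehog (0.000247) and neural (0.0179) lists did.

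Leaving out each array in turn gave 2199 to 3275 differing genes, 1020 to 1362 higher, 1758 to 2155 by at least 2-fold and 1179 (without ectoderm replicate 4) to 1916 lower. Adjusted p ran from 0.00856 (without AER replicate 2) to 0.9749 for the erythroid list, from 0.0131 to 0.0648 (without AER replicate 2, and 0.0517 without ectoderm replicate 3) for the immediate-early list, and from 0.00312 (without ectoderm replicate 3, and 0.0428 without ectoderm replicate 1) to 0.138 for the 5' Hox list.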

Other observations

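The added gene lists in this part were tested after the main results had been seen, and all of their genes outside the naming rule were chosen after their values were seen. The Dlx, Sp, Hoxa, Hoxc, Hoxd, placode, enamel and sphingolipid lists hold genes already seen in the main results, so they are no independent evidence and are described without a test. Members with no probe past the filter were left out: 8 of 12 enamel, 4 of 10 placode, 4 of 21 sphingolipid, 3 of 17 connective tissue, 3 of 10 Hoxb, 1 of 9 Hoxc and 2 of 9 Hoxd genes. The Dlx homeobox family, which patterns appendages, included Dlx2, Dlx5 and Dlx6 among the known AER genes, and all 6 of its genes were higher in AER, with a median of 3.26 (1.69 under epithelial centring, with 4 higher, and 2.26 to 2.29 with normexp and the authors' values). Dlx1 led with 4.21 (3.61 under normexp), and Dlx4 and Dlx3 rose by 2.19 and 1.16 (Dlx4 1.47 under normexp, Dlx3 -0.42 under epithelial centring). Of 9 Sp zinc finger genes, 5 rose and 1 fell, with a median of 0.53 that was -1.05 under epithelial centring and 0.36 under normexp, where 3 rose. Beyond Sp6, Sp8 and Sp9, Sp7 and Sp4 gave 1.24 and 0.53, calls lost under normexp (0.43 and 0.22, adjusted p = 0.157 and 0.423), and -0.34 and -1.05 under that centring. Among Hox clusters, 4 of 8 Hoxc genes rose and 0 fell, with a median of 1.02 that was -0.55 under epithelial centring and 0.59 under normexp, where 3 rose. Hoxc8 was at least 3.98-fold higher, and 2.03-fold under normexp. Hoxa genes had 1 higher and 2 lower of 11 (median -0.08, -0.22 under normexp, and 0.03 with the percentile over probes above background) and Hoxd genes 1 and 1 of 7 (median 0.39, and -1.18 under epithelial centring). Hoxb genes, with 2 higher and 0 lower of 7 (median -0.35, and -0.60 under normexp, mean 0.33), did not pass as a list (adjusted p = 0.535). Hoxb3, at 3.02 (adjusted p = 0.000957), and Hoxb9, at 2.81 (1.21 under normexp), were higher.

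Genes shared with other ectodermal organs were among those higher in AER. Of 12 enamel and tooth genes, the 4 past the filter rose, with a median of 3.31, or 3.15 with Ambn at its bound. That median was 1.73 under epithelial centring and 2.06 to 2.09 with normexp and the authors' values. The other members, among them Amelx and Enam, had probes on the array but none past the filter. Ambn passed it through the AER arrays alone, so these values do not describe the list as a whole. Fam20a and Fam20c, a pair of secretory kinase genes, rose by 4.67 (3.45 under normexp) and 1.96, and Fam83h by 1.34 (-0.24 under epithelial centring). Of 6 ectodermal placode genes 2 rose and 1 fell, with a median of 0.49 that was 0.27 under normexp and -1.09 under epithelial centring. Edar, the receptor of ectodysplasin, was at least 4.46-fold higher (adjusted p = 1.35e-05; 2.26-fold under normexp) and its adaptor Edaradd rose by 1.16 (-0.41 under epithelial centring), while the ligand gene Eda was lower at -1.35 (-0.71 under normexp). Sphingolipid genes had 4 of 17 higher and 0 lower, with a median of 0.03 (0.18 under normexp) and a mean of 0.79, and a median of -1.55 under epithelial centring. Beyond Smpd3, the serine palmitoyltransferase gene Sptlc3 was at least 18.8-fold higher, the sphingomyelin synthase gene Sgms2 at least 2.52-fold (5.29-fold and 1.62-fold under normexp) and the ceramide synthase gene Cers3 higher by 1.66.

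The lists behind the open explanations of the muscle and Hox patterns gave these values. Of 20 skeletal muscle contractile genes, 17 were lower in AER and 0 higher, with a median of -3.05, or -2.82 with 9 genes at their bounds and -1.59 to -1.47 with normexp and the authors' values (adjusted p = 2.89e-12, and adjusted p = 0.112 with an estimated correlation). Tendon and fibrous connective tissue genes had 11 of 14 lower and 1 higher, with a median of -2.08, and -1.47 to -1.41 with those values (adjusted p = 1.05e-07, and adjusted p = 0.0769 with an estimated correlation). Proximal limb mesenchyme genes had 8 of 9 lower, with a median of -2.49, and -1.92 to -1.88 with those values (adjusted p = 8.38e-08, and adjusted p = 0.108 with an estimated correlation). Distal limb mesenchyme genes had 4 of 7 higher and 0 lower, with a median of 1.64, and 0.06 under epithelial centring with 2 higher and 2 lower (adjusted p = 0.00021, and adjusted p = 0.0769 with an estimated correlation). Pan-mesenchymal genes had 4 of 11 lower and 0 higher, with a median of -0.42 (adjusted p = 0.0542). Above background on all AER arrays were 7 of the 20 contractile genes, 9 of the 14 connective tissue genes, 7 of the 9 proximal and all 7 distal genes, against 17, 13, 9 and 6 on all ectoderm arrays.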
